A study of Mus musculus with 12 samples.

How the data were processed

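The samples were RNA-seq libraries from resident peritoneal macrophages of C57BL/6 mice, 3 in each of 4 groups (MOPS, HEPES, MOPS with LPS, HEPES with LPS). Total RNA was isolated with Trizol, and libraries were prepared with the NEBNext Ultra RNA kit. The processing notes in the labels name CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the mouse build mm10, without stating their roles. The strand setting, the annotation release and the authors' test are not given in the sources used here.

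The deposited table holds, per the file headers, raw counts for each gene and library, which are whole numbers summing to 20114613 to 24734853 per library. Its FPKM columns were made by the authors: checked against the counts and gene lengths in the table, each equals the count divided by length and by a size factor of the library, not by its total. The other columns are the authors' group means, log2 fold changes, p-values and adjusted p-values in 4 comparisons, and these hold other units than counts or FPKM. In their columns LPS comparisons run untreated over LPS, so their sign was turned for comparison. Their adjusted p-values equal 1 exactly in 6735, 6412, 3959 and 3565 genes of the comparisons at rest, under LPS, in MOPS and in HEPES. Of 54532 gene IDs, 54495 were found in GENCODE vM21 and 98.3% of these had the same coordinates. Where 2 IDs share a symbol, the one with most counts keeps it.

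Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes with too few counts for the groups were removed by filterByExpr, leaving 14506, libraries were scaled by TMM factors (1.22 in MOPS, 1.20 in HEPES, 0.854 in MOPS with LPS and 0.801 in HEPES with LPS), and a means model of the 4 groups with robust quasi-likelihood dispersion was fitted to all 12 libraries, with 8 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. The contrasts were MOPS over HEPES without LPS, MOPS over HEPES with LPS, LPS over untreated in each medium, the interaction (the LPS change in MOPS minus that in HEPES) and the mean LPS change. The common biological coefficient of variation was 4.62%. Within groups, pairs of libraries differed with a chi-square per degree of freedom of 2.66 to 6.54 over genes with at least 20 counts, above the counting error of 1, and correlated at 0.991 to 0.994.

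Lists of genes were fixed before the data were examined: 23 functional lists and 5 lists of markers of other cell types, 28 in all. The lists were glycolysis, TCA cycle, nuclear oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, cholesterol synthesis and uptake, LXR targets with fatty acid synthesis, lysosome, proton sensing with acid-base transport, cAMP-CREB targets, ATF4 integrated stress response, unfolded protein response, NRF2 targets, hypoxia targets, NF-kappaB feedback, inflammatory cytokines with chemokines and enzymes, type I interferon response, TLR4 pathway, immediate-early genes, alternative activation, large peritoneal macrophage identity, antigen presentation, cell cycle, and B cell, T and NK cell, granulocyte and mast cell, dendritic and small peritoneal macrophage, and mesothelial, stromal and endothelial markers. The competitive camera test of limma 3.58.1 used a preset correlation of 0.01, and was repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. P-values were adjusted over the lists of each contrast. Counts per list are over all genes tested, and also adjusted over the list alone where that differs. For each called list the median, mean and camera direction had the same sign. Some lists share members, as Slc7a11 is among both NRF2 targets and ATF4 genes.

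The named genes were chosen by a rule fixed before the data were examined: for each contrast the 8 largest changes in each direction among protein-coding genes with adjusted p under 0.05, non-overlapping groups (except for the interaction; chance gives this for 10% of genes with 3 against 3) and a mean of at least 10 CPM in the higher group, up to 4 members of each list by smallest p, and a set list that includes Gpr65, Gpr132, Tnf, Il6, Il1b, Nos2, Arg1 and Gata6. Some genes that the rule names are not reported here. Ifnb1, also on it, was not tested because it had too few counts. Of 306 named genes, 28 overlap another annotated gene that holds at least 10% of their count, 23 of them on the opposite strand. Where a group had 0 counts, a fold is given against 3 counts over the group, and with 1 to 3 counts as a ratio with an exact 95% interval. These intervals cover counting error only.

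The methods were tested on simulated data made from these counts, with 50 genes changed at each size. For the comparison at rest (14054 genes tested), edgeR recovered 74%, 72%, 94% and 100% of genes changed 1.5, 2, 3 and 4-fold, with 6 false calls. For the interaction (14040 genes tested) the shares were 46%, 68%, 88% and 88% with 13 false calls. False calls made up 3.41% of all edgeR calls at rest and 8.23% in the interaction. The share in the interaction is above that set by the adjusted p threshold. With a GC trend added there were 4049 false calls without the offset for it and 5 with it. Few genes were changed in the simulations, whereas in the data 39.43% were called in the interaction and 76.86% with LPS in HEPES. The simulations therefore do not test the scaling of libraries when a large part of the genes changes.

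Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, only the groups of a contrast, a fold minimum of 2, limma-trend on log2(FPKM + 1), each library left out in turn, and, for lists, an estimated correlation and fry. Added after seeing the data were scaling by total counts alone, an offset for a smooth trend on GC content and exonic length (GC known for 14492 of 14506 genes), list counts under 5 alternatives, and list tests with each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.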

Results

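Resident peritoneal macrophages of C57BL/6 mice were kept for 24 h in DMEM buffered with MOPS or with HEPES, and then either left untreated or given LPS at 10 ng/ml for 2 h. LPS is the bacterial cell-wall component that Toll-like receptor 4 senses. Gene expression was measured by RNA-seq in 12 libraries, 3 in each of 4 groups: MOPS, HEPES, MOPS with LPS and HEPES with LPS. The study's title concerns extracellular acidity. Its design text names pH 6.8 and pH 7.4 and then MOPS and HEPES in that order, so pH 6.8 is taken to go with MOPS and pH 7.4 with HEPES from word order alone. Because buffer and pH change together, every comparison of media below is of the medium as a whole. Library totals were 20114613 to 24734853 counts in MOPS and 22433773 to 24669239 in HEPES. With LPS they were 21210474 to 24521749 in MOPS and 22447187 to 23506654 in HEPES. Of 54532 genes in the table, 14506 had enough counts to be tested. The p-values measure the spread between these libraries only, since the labels do not say whether replicates were separate animals or cultures.

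LPS separated the libraries first and the medium second. Principal component 1 held 73.2% of the variance and principal component 2 held 14.4%. On component 1 the untreated libraries lay at -74.3 to -69.0, while the MOPS libraries with LPS reached 53.8 to 59.2 and the HEPES libraries with LPS reached 86.7 to 88.7. Named values below are log2 fold changes ± standard error, or group means in CPM (counts scaled to library size and composition) ± SD with n = 3. The standard error was taken as the size of the log2 change divided by the square root of the quasi-likelihood F statistic. It is therefore an approximation, and it can be too small where a group has few counts. After each list of genes stand in parentheses its median log2 change, its adjusted p by the camera test against all other genes, and the same with an estimated correlation between genes.

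**Figure D1:**
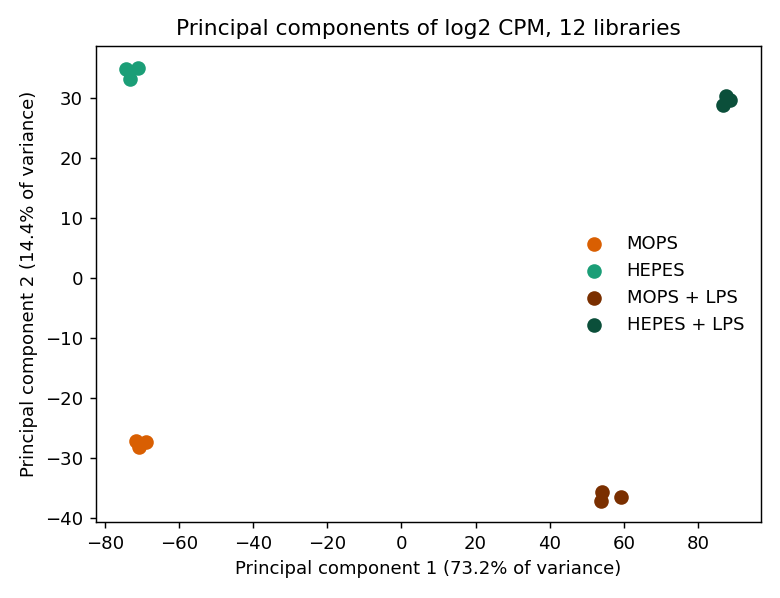
Each point is 1 library, placed by its scores on the first principal components of log2 CPM (axes in score units, with percent of variance). The 4 groups of 3 form separate clusters, and the LPS libraries lie at 53.8 to 59.2 in MOPS and at 86.7 to 88.7 in HEPES on component 1.

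The comparison of the media without LPS asked what the MOPS medium, taken as the acidic one, did to resting macrophages. Genes of lipid burning and of antioxidant defence were higher in MOPS, and genes of cholesterol synthesis were lower. Pdk4, the kinase that shuts pyruvate out of the citric acid cycle, stood at 53.7 ± 0.522 CPM (SD, n = 3) in MOPS and 0.199 ± 0.0131 CPM in HEPES, a log2 fold change of 8.04 ± 0.14 (adjusted p = 2.80e-28, edgeR). Angptl4, a secreted inhibitor of lipoprotein lipase, was at 153 ± 4.02 CPM against 1.66 ± 0.258 CPM (6.52 ± 0.085). Arg1, the arginase that marks alternatively activated macrophages, was at 509 ± 48.7 CPM against 37.7 ± 5.11 CPM (3.75 ± 0.14). Idi1, an enzyme of isoprenoid and sterol synthesis, was at 2.79 ± 0.0886 CPM against 33.0 ± 0.679 CPM (-3.56 ± 0.087). In the mm10 coordinates of the table, Pdk4 is ENSMUSG00000019577 on chromosome 6 from 5483351 to 5496309, Angptl4 is ENSMUSG00000002289 on chromosome 17 from 33773750 to 33781575, Arg1 is ENSMUSG00000019987 on chromosome 10 from 24915221 to 24927484 and Idi1 is ENSMUSG00000058258 on chromosome 13 from 8885501 to 8892451.

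The cholesterol synthesis and uptake genes were lower in MOPS as a set: all 20 measured members, without exception (median -2.15, adjusted p = 5.82e-24, adjusted p = 0.00723 with an estimated correlation). Among them were Sqle (-3.12 ± 0.079) and Hsd17b7 (-2.96 ± 0.086). Targets of NRF2, the transcription factor of the oxidative stress response, were all higher, 17 of 17 (median 1.17, adjusted p = 4.98e-19, adjusted p = 0.0157 with an estimated correlation). Hmox1, which degrades heme, was at 2425 ± 93.6 CPM in MOPS and 497 ± 16.5 CPM in HEPES (2.29 ± 0.044), and Gsr, Gclm and Cat changed by 1.76 ± 0.037, 1.81 ± 0.04 and 1.56 ± 0.044. Hmox1 is ENSMUSG00000005413 on chromosome 8 from 75093621 to 75100589. Of 20 fatty acid oxidation genes, 17 were higher and 2 lower (median 0.61, adjusted p = 1.76e-10, adjusted p = 0.00723 with an estimated correlation), with Acadl at 1.44 ± 0.046, Cpt1a at 1.32 ± 0.044 and Slc25a20 at 1.51 ± 0.069.

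Other sets were called between the media without LPS. The unfolded protein response had 11 of 14 higher and 0 lower (median 0.21, adjusted p = 1.32e-05, adjusted p = 0.367 with an estimated correlation). Hypoxia (HIF-1) targets had 13 of 20 higher and 3 lower (median 0.31, adjusted p = 0.00281, adjusted p = 0.0862 with an estimated correlation). Hilpda was at 2.39 ± 0.077 and Ndrg1 at -1.29 ± 0.12. The type I interferon response had 0 of 28 higher and 18 lower, or 0 and 19 adjusted over the list alone (median -0.66, adjusted p = 2.23e-05, adjusted p = 0.389 with an estimated correlation). Oas2 was at -1.21 ± 0.15 and Cmpk2 at -1.56 ± 0.19. The mitochondrially encoded genes had 0 of 13 higher and 9 lower, or 0 and 12 adjusted over the list alone (median -0.44, adjusted p = 1.73e-04, adjusted p = 0.367 with an estimated correlation). Lysosome genes had 5 of 30 higher and 18 lower (median -0.21, adjusted p = 5.22e-04, adjusted p = 0.438 with an estimated correlation), and antigen presentation genes had 1 of 17 higher and 11 lower (median -0.32, adjusted p = 0.00184, adjusted p = 0.484 with an estimated correlation). B cell markers had 6 of 10 higher and 0 lower (median 0.70, adjusted p = 0.0136, adjusted p = 0.665 with an estimated correlation), with Ighm at 114 ± 0.957 CPM in MOPS and 52.9 ± 14.6 CPM in HEPES. Without HEPES replicate 4 the B cell list was not called (adjusted p = 0.0519, with 2.87e-04 to 0.665 over all alternatives).

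The other 18 lists were not called between the media without LPS. Of these, the TCA cycle, proton sensing, cAMP-CREB, NF-kappaB feedback and mesothelial lists had medians, means or tests of unlike sign. Members of the 18 lists split as follows: glycolysis 9 of 20 higher and 6 lower, TCA cycle 4 of 20 higher and 4 lower, nuclear genes of oxidative phosphorylation 5 of 30 higher and 9 lower, LXR targets and fatty acid synthesis 4 of 13 higher and 7 lower, or 4 and 8 adjusted over the list alone, and proton sensing and acid-base transport 7 of 14 higher and 5 lower. The cAMP-CREB targets had 8 of 19 higher and 4 lower, the ATF4 integrated stress response 12 of 20 higher and 7 lower, NF-kappaB feedback genes 6 of 19 higher and 5 lower, inflammatory cytokines, chemokines and enzymes 5 of 28 higher and 9 lower, and TLR4 pathway components 12 of 20 higher and 5 lower, or 13 and 5 adjusted over the list alone. Immediate-early genes had 6 of 17 higher and 6 lower, or 7 and 6 adjusted over the list alone, alternative activation 5 of 16 higher and 8 lower, large peritoneal macrophage identity 6 of 21 higher and 9 lower and cell cycle 2 of 20 higher and 7 lower. Among markers of other cells, T and NK cell markers had 0 of 2 higher and 1 lower, granulocyte and mast cell markers 2 of 9 higher and 3 lower, dendritic cell and small peritoneal macrophage markers 3 of 9 higher and 2 lower, and mesothelial, stromal and endothelial markers 0 of 7 higher and 0 lower.

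Individual genes of interest moved without LPS as well. Among receptors that sense protons, Gpr65 was lower in MOPS (-0.92 ± 0.07), while Gpr132 (0.78 ± 0.10) was higher. The chemokine genes Ccl2 (-2.96 ± 0.13) and Cxcl13 (-3.53 ± 0.19) and the cytokine gene Tnf (-0.95 ± 0.095) were lower, and Ptgs2, the inducible cyclooxygenase, was higher (1.81 ± 0.29). Gpr65 is ENSMUSG00000021886 on chromosome 12 from 98268635 to 98276644 and Ccl2 is ENSMUSG00000035385 on chromosome 11 from 82035571 to 82037453. Slc2a1 (0.47 ± 0.092), Abca1 (0.50 ± 0.047) and Gata6 (0.28 ± 0.058) were higher. Il10 was lower (-2.42 ± 0.71, adjusted p = 0.0138), but the call was lost without MOPS replicate 1 (adjusted p = 0.0516) or MOPS replicate 2 (adjusted p = 0.0635), and over all alternatives the adjusted p was 4.02e-05 to 0.0635. Hk2 at -0.16 ± 0.062 (adjusted p = 0.0403) was not called by DESeq2 (adjusted p = 0.09) or with RLE size factors (adjusted p = 0.0988), with 0.0136 to 0.177 over all alternatives, 7 of the left-out libraries among those that lost the call. Ldha (0.08 ± 0.039), Acod1 (-0.07 ± 0.15) and Il1b (-0.65 ± 0.30) did not pass the test.

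In all, 3518 genes were higher and 3687 lower in MOPS without LPS, 49.7% of those tested, at an adjusted p under 0.05 (edgeR). The median fold change of the called genes was 1.31, and 487 genes were higher and 690 lower by at least 2-fold. Of the genes called by the authors' deposited table in this comparison (3240 higher and 3026 lower), 6134 were called here in the same direction and 0 in the opposite one.

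With LPS present, the comparison of the media asked how the same medium changed LPS-treated macrophages. Cholesterol genes were lower in MOPS, and antioxidant and fatty acid oxidation genes were higher, as sets that were also called with an estimated correlation between genes. Inflammatory genes were lower in part, as a set whose call was lost with that correlation. Ccl2, a monocyte chemoattractant, was at 52.1 ± 2.68 CPM (SD, n = 3) in MOPS with LPS and 521 ± 39.7 CPM in HEPES with LPS (-3.32 ± 0.073, adjusted p = 9.42e-16, edgeR). Il12b, a subunit of interleukin-12 and interleukin-23, was at 30.8 ± 4.87 CPM against 124 ± 10.6 CPM (-2.02 ± 0.10). Ccl7 (-4.32 ± 0.11), Csf2 (-2.91 ± 0.071), Edn1 (-3.99 ± 0.24) and Sele (-5.21 ± 0.21) were lower too. Gata6, the transcription factor that maintains large peritoneal macrophages, was at 48.1 ± 5.14 CPM against 133 ± 1.24 CPM (-1.47 ± 0.054). The large peritoneal macrophage identity list, to which Gata6 belongs, had a median of 0.0089 in this comparison and was not called. Il12b is ENSMUSG00000004296 on chromosome 11 from 44400063 to 44414033, Gata6 is ENSMUSG00000005836 on chromosome 18 from 11052508 to 11085635 and Sele is ENSMUSG00000026582 on chromosome 1 from 164048234 to 164057677.

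Inflammatory cytokines, chemokines and enzymes had 1 of 28 higher and 18 lower, or 1 and 21 adjusted over the list alone (median -0.58, adjusted p = 2.40e-05, adjusted p = 0.253 with an estimated correlation). Nos2 (-2.13 ± 0.19), Il6 (-1.04 ± 0.12), Il1b (-0.94 ± 0.14) and Ptgs2 (-0.88 ± 0.12) were lower. DESeq2 did not call Il6 (adjusted p = 0.129; 9.92e-07 to 0.129 over all alternatives). Tnf (-0.13 ± 0.063, adjusted p = 0.0941), Cxcl10 (-0.23 ± 0.089, adjusted p = 0.0524) and Acod1 (-0.17 ± 0.10, adjusted p = 0.198) did not pass. The NF-kappaB feedback genes had 2 of 19 higher and 15 lower (median -0.48, adjusted p = 2.40e-05, adjusted p = 0.43 with an estimated correlation). Traf1 was at -1.23 ± 0.057 and Tnfaip3 at -0.82 ± 0.044. The type I interferon response had 1 of 28 higher and 24 lower, or 2 and 24 adjusted over the list alone (median -0.86, adjusted p = 4.79e-06, adjusted p = 0.337 with an estimated correlation). Antigen presentation genes had 3 of 17 higher and 10 lower (median -0.23, adjusted p = 0.0182, adjusted p = 0.471 with an estimated correlation). Cd80 was at -1.85 ± 0.052 and Cd40 at -1.10 ± 0.045. The ATF4 integrated stress response had 4 of 20 higher and 11 lower (median -0.23, adjusted p = 0.0182, adjusted p = 0.471 with an estimated correlation), with Asns at -1.58 ± 0.061, and the unfolded protein response had 2 of 14 higher and 8 lower, or 2 and 9 adjusted over the list alone (median -0.14, adjusted p = 0.012, adjusted p = 0.471 with an estimated correlation). Herpud1 was at -0.99 ± 0.037.

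Metabolic sets also differed between the media under LPS. The cholesterol genes had 1 of 20 higher and 18 lower (median -1.69, adjusted p = 1.69e-13, adjusted p = 0.0366 with an estimated correlation). Idi1 was at -3.00 ± 0.093. NRF2 targets had 16 of 17 higher and 0 lower (median 1.05, adjusted p = 6.95e-13, adjusted p = 0.0496 with an estimated correlation). Hmox1 was at 2.05 ± 0.043. The fatty acid oxidation genes had 16 of 20 higher and 1 lower, or 18 and 1 adjusted over the list alone (median 0.68, adjusted p = 3.20e-08, adjusted p = 0.0327 with an estimated correlation). Acadl was at 1.47 ± 0.048. Pdk4 had 2 counts in all over the HEPES libraries with LPS, and its level was 242-fold higher in MOPS, with an exact 95% counting interval of 66.7 to 2005. Its fitted log2 value of 7.72 became 10.70 without HEPES with LPS replicate 12. Glycolysis genes had 13 of 20 higher and 4 lower (median 0.29, adjusted p = 0.012, adjusted p = 0.471 with an estimated correlation). Eno1 was at 0.77 ± 0.039 and Hk2 at -0.98 ± 0.053. Hypoxia targets had 13 of 20 higher and 5 lower, or 14 and 5 adjusted over the list alone (median 0.51, adjusted p = 0.0336, adjusted p = 0.253 with an estimated correlation), and were not called without MOPS with LPS replicate 7 (adjusted p = 0.0556, with 1.64e-05 to 0.253 over all alternatives). The mitochondrially encoded genes had 0 of 13 higher and 6 lower (median -0.21, adjusted p = 0.0412, adjusted p = 0.471 with an estimated correlation), and were not called without MOPS with LPS replicate 7 (adjusted p = 0.0703) or HEPES with LPS replicate 11 (adjusted p = 0.0701), with 0.00444 to 0.471 over all alternatives.

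Arg1 (3.81 ± 0.15), Angptl4 (5.37 ± 0.092) and the iron exporter gene Slc40a1 (3.89 ± 0.14) were higher in MOPS with LPS. The alternative activation list, to which Arg1 belongs, had 4 of 16 higher and 10 lower, or 5 and 10 adjusted over the list alone there (median -0.44) and was not called (adjusted p = 0.27). Gpr65, lower in MOPS without LPS, was higher with it (1.25 ± 0.10). Gpr132 was lower (-0.25 ± 0.06). Slc2a1 was at 0.26 ± 0.087 (adjusted p = 0.0257). Its call was lost on leaving out MOPS with LPS replicate 7 or 8 or HEPES with LPS replicate 10 or 11. It was also lost in edgeR with the GC and length offset (adjusted p = 0.0757). Over all alternatives the adjusted p of Slc2a1 was 0.00109 to 0.169. B cell markers were all higher in MOPS with LPS, 10 of 10 higher and 0 lower (median 1.71, adjusted p = 1.74e-05, adjusted p = 0.337 with an estimated correlation), with Ighm at 68.0 ± 4.24 CPM against 13.6 ± 0.512 CPM.

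In all, 3904 genes were higher and 3897 lower in MOPS with LPS, 53.8% of those tested, with a median fold change of 1.39 and with 899 higher and 624 lower by at least 2-fold. Scaling by total counts alone gave 4885 higher and 2942 lower, 62.41% higher against 50.04%. Of the genes higher in MOPS without LPS, 2004 were also higher with LPS, where 947 would be shared if the comparisons were independent, and 529 were lower. Of those lower without LPS, 1850 were also lower with it, where 991 would be shared, and 412 were higher. Across genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.546 and a Spearman rho of 0.462. The authors' table called 3123 genes higher and 3146 lower, of which 6195 were called here in the same direction and 0 in the opposite one.

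**Figure D2:**
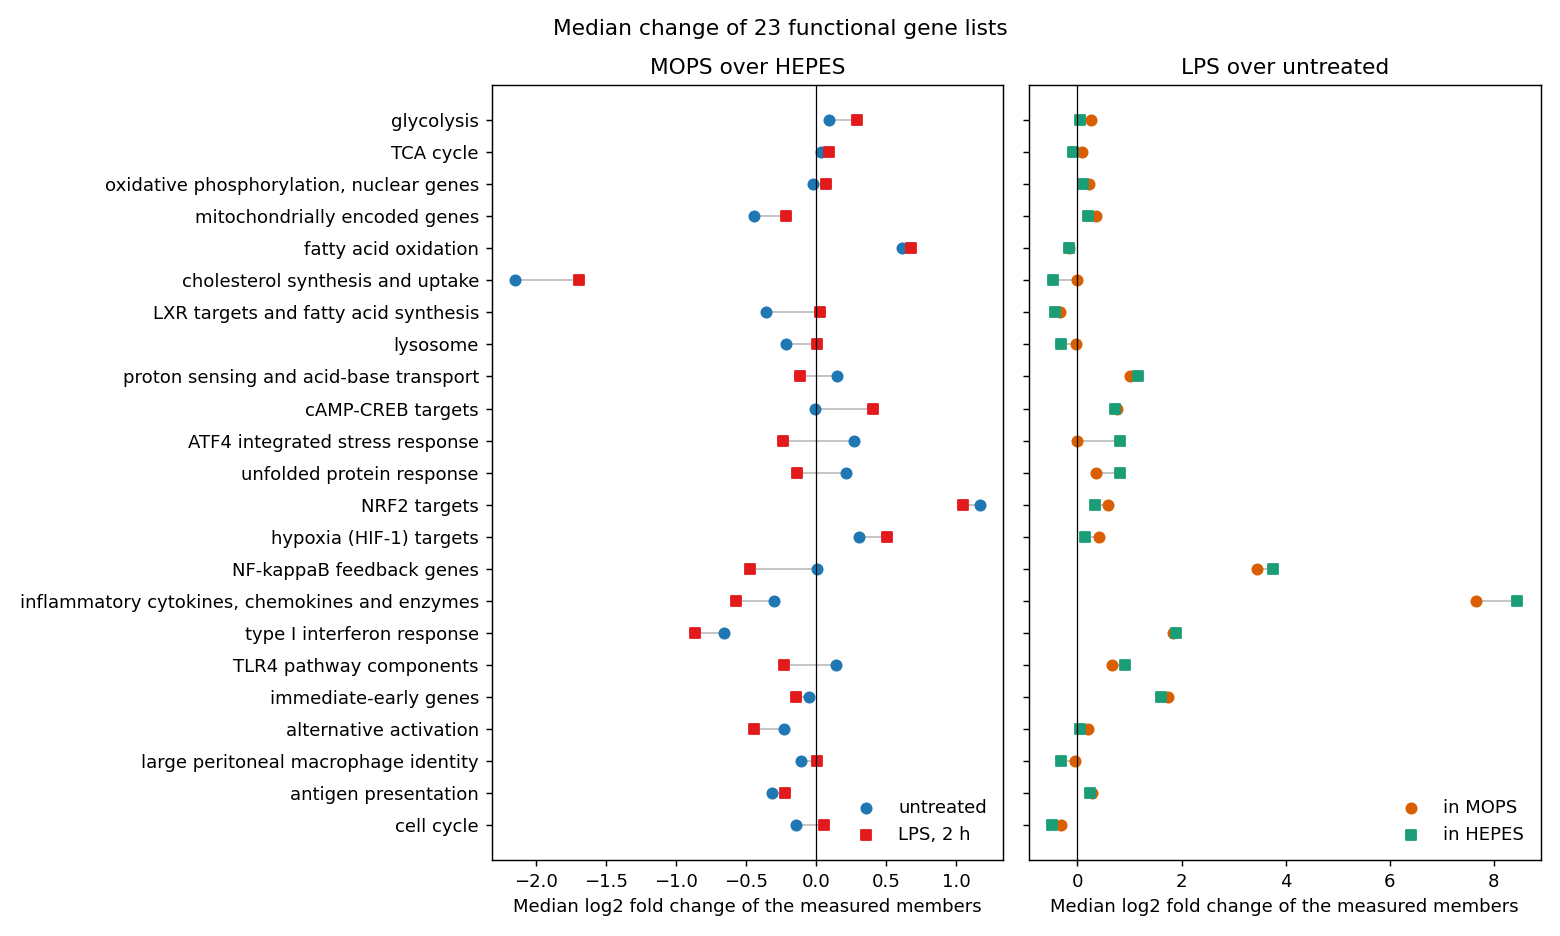
Points give the median log2 fold change of the measured members of 23 functional gene lists, on the left for MOPS over HEPES (untreated and with LPS) and on the right for LPS over untreated (in each medium). Cholesterol synthesis lay at -2.15 and -1.69 and NRF2 targets at 1.17 and 1.05 on the left. On the right, glycolysis lay at 0.26 in MOPS and 0.05 in HEPES. Scaling by total counts alone, which is not drawn, moves all genes. With it glycolysis goes to -0.25 in MOPS and -0.54 in HEPES, or 0.30 and 0.13 above the median of all genes.

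**Figure D3:**
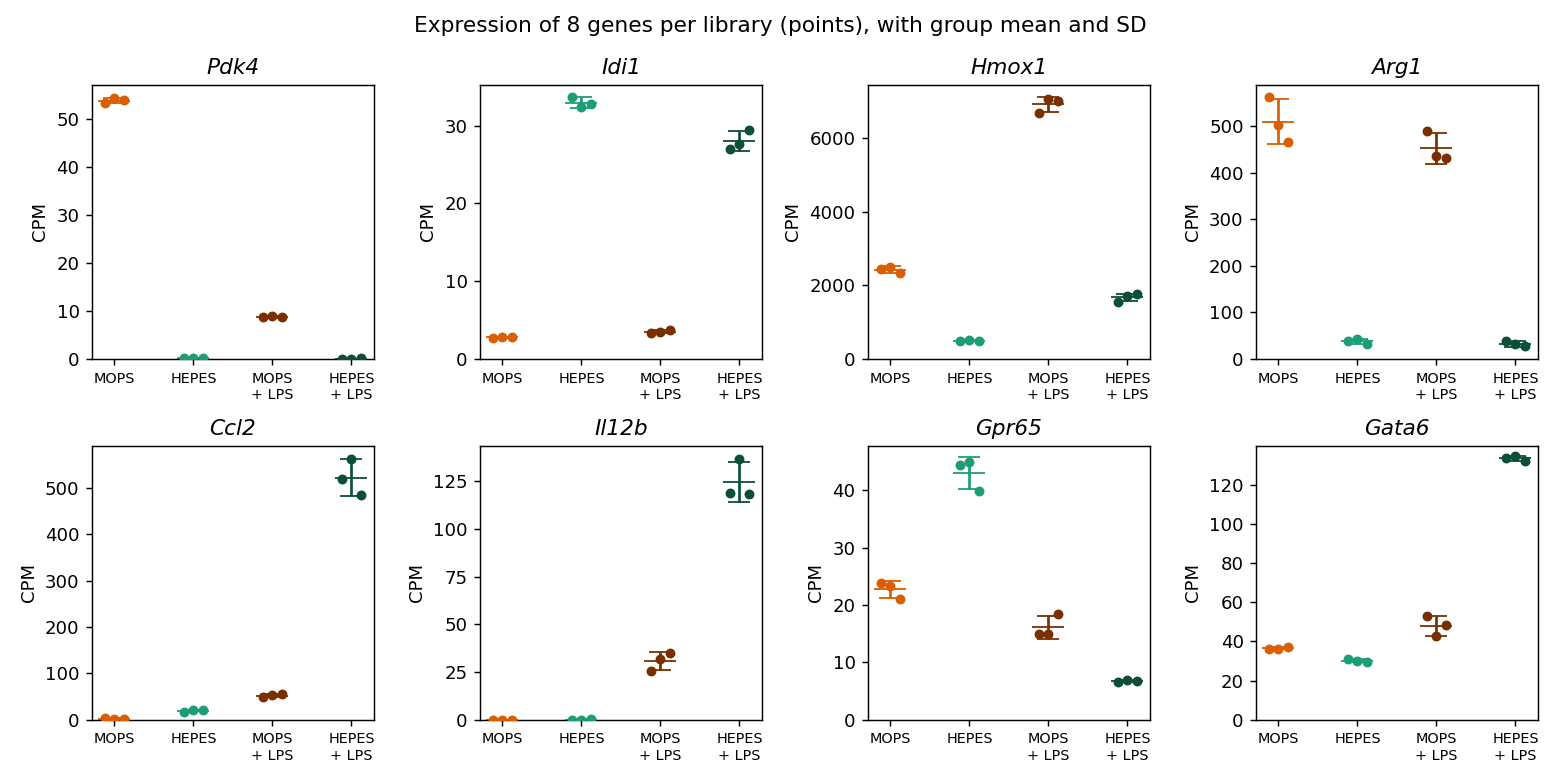
Points are CPM of 8 genes in each of the 12 libraries, with the group mean and SD as bars. Pdk4, Hmox1 and Arg1 were higher in MOPS than in HEPES with and without LPS, Idi1, Ccl2 and Il12b (the last with LPS) were lower, and Gpr65 was lower in MOPS without LPS (-0.92) and higher with it (1.25).

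The comparison of LPS with no treatment within each medium asked what the endotoxin response was in that medium. The inflammatory programme rose in both. All 28 measured inflammatory cytokines, chemokines and enzymes were higher with LPS in MOPS (median 7.65, adjusted p = 8.43e-20, adjusted p = 0.0268 with an estimated correlation) and in HEPES (median 8.45, adjusted p = 7.81e-17, adjusted p = 0.0444 with an estimated correlation). Tnf went from 12.5 ± 1.91 to 8184 ± 269 CPM (SD, n = 3) in MOPS and from 24.2 ± 1.59 to 8972 ± 598 CPM in HEPES. Lif rose by 12.55 ± 0.20 on the log2 scale in MOPS and 13.44 ± 0.21 in HEPES, Il6 by 12.04 ± 0.28 and 11.11 ± 0.23, Cxcl10 by 10.60 ± 0.23 and 9.77 ± 0.21, and Il1b by 10.41 ± 0.23 and 10.70 ± 0.22. Some of these fitted values rest on few untreated counts. Leaving out HEPES replicate 5 moved Il6 in HEPES to 12.23, and leaving out MOPS replicate 1 moved Lif in MOPS to 13.21.

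Several induced genes had almost no counts in untreated HEPES libraries, so their size there is a bound or a ratio with its counting interval. Against 3 counts over the group, Plet1 was at least 2742-fold higher with LPS, Has1 at least 1666-fold and Sele, the leukocyte adhesion molecule E-selectin, at least 563-fold higher. Csf2, with 3 untreated counts, was 10460-fold higher (exact 95% interval 3579 to 50730), Ereg, with 1, was 12800-fold higher (2297 to 505700), and Il23a, with 3, was 4725-fold higher (1616 to 22920). Nos2, the inducible nitric oxide synthase, had 2 untreated counts in MOPS and was 154-fold higher with LPS there (42.2 to 1282). Single libraries moved the fitted log2 values of such genes. Without HEPES replicate 5, Csf2 in HEPES went from 13.15 to 13.96 and Ereg from 13.10 to 14.74. Without HEPES replicate 4, Il23a went to 14.88. Nos2 in MOPS went to 6.41 without MOPS replicate 2 and to 9.49 without MOPS replicate 3.

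The NF-kappaB feedback genes rose in full in both media, 19 of 19 (median 3.46, adjusted p = 1.15e-17, adjusted p = 0.135 with an estimated correlation in MOPS; median 3.76, adjusted p = 4.78e-15, adjusted p = 0.155 with an estimated correlation in HEPES). Nfkbiz rose by 5.51 ± 0.046 and 5.05 ± 0.044. Immediate-early genes had 15 of 17 higher and 1 lower, or 16 and 1 adjusted over the list alone in MOPS (median 1.74, adjusted p = 1.75e-08, adjusted p = 0.18 with an estimated correlation) and 13 of 17 higher and 3 lower in HEPES (median 1.61, adjusted p = 1.29e-04, adjusted p = 0.371 with an estimated correlation). Maff was at 5.14 ± 0.065 and 5.84 ± 0.068. TLR4 pathway components had 15 of 20 higher and 3 lower, or 15 and 4 adjusted over the list alone (median 0.67, adjusted p = 4.82e-05, adjusted p = 0.167 with an estimated correlation) and 14 of 20 higher and 3 lower (median 0.92, adjusted p = 2.75e-05, adjusted p = 0.155 with an estimated correlation). Tlr2 was at 4.79 ± 0.059 and 4.38 ± 0.057. The interferon response had 17 of 28 higher and 7 lower, or 18 and 7 adjusted over the list alone (median 1.83, adjusted p = 8.77e-04, adjusted p = 0.419 with an estimated correlation) and 22 of 28 higher and 1 lower (median 1.89, adjusted p = 1.06e-05, adjusted p = 0.371 with an estimated correlation). Isg15 was at 6.37 ± 0.081 and 6.04 ± 0.073.

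Stress and metabolic sets also moved with LPS. NRF2 targets had 12 of 17 higher and 2 lower, or 13 and 3 adjusted over the list alone in MOPS (median 0.58, adjusted p = 8.77e-04, adjusted p = 0.406 with an estimated correlation) and 11 of 17 higher and 3 lower, or 11 and 4 adjusted over the list alone in HEPES (median 0.33, adjusted p = 0.0114, adjusted p = 0.46 with an estimated correlation), where the median turned to -0.25 with total-count scaling, 0.42 above the median of all genes. Txnrd1 was at 2.29 ± 0.039 and 2.84 ± 0.04. The unfolded protein response had 11 of 14 higher and 3 lower in MOPS (median 0.36, adjusted p = 0.00472, adjusted p = 0.423 with an estimated correlation), a median that turned to -0.16 with total-count scaling, 0.39 above the median of all genes, and 13 of 14 higher and 1 lower in HEPES (median 0.81, adjusted p = 1.89e-05, adjusted p = 0.371 with an estimated correlation). In HEPES the ATF4 integrated stress response had 13 of 20 higher and 5 lower (median 0.82, adjusted p = 0.0125, adjusted p = 0.535 with an estimated correlation) and lysosome genes had 4 of 30 higher and 22 lower (median -0.32, adjusted p = 0.00193, adjusted p = 0.46 with an estimated correlation). The proton sensing and acid-base transport genes had 7 of 14 higher and 2 lower in MOPS (median 1.0016, adjusted p = 0.0233, adjusted p = 0.215 with an estimated correlation), with Gpr132 at 2.93 ± 0.075. In HEPES they had 10 of 14 higher and 4 lower, short of a call (median 1.16, adjusted p = 0.0506, adjusted p = 0.371 with an estimated correlation). The cAMP-CREB targets had 13 of 19 higher and 5 lower in MOPS (median 0.76, adjusted p = 0.0203, adjusted p = 0.406 with an estimated correlation), with Nr4a3 at 4.72 ± 0.08, and 12 of 19 higher and 5 lower in HEPES, short of a call (median 0.72, adjusted p = 0.065, adjusted p = 0.46 with an estimated correlation). Neither list was called in the interaction (adjusted p = 0.372 and 0.774).

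Further sets were called with LPS in MOPS with small medians. Scaling by total counts alone moves all genes down with LPS and turned these medians negative, but each stayed above the median of all genes (-0.55). Nuclear genes of oxidative phosphorylation had 19 of 30 higher and 2 lower, or 20 and 2 adjusted over the list alone (median 0.22, adjusted p = 0.0062, adjusted p = 0.447 with an estimated correlation, turning to -0.29, 0.25 above all genes). Mitochondrially encoded genes had 10 of 13 higher and 0 lower (median 0.36, adjusted p = 0.0168, adjusted p = 0.423 with an estimated correlation, turning to -0.15, 0.40 above all genes), glycolysis 11 of 20 higher and 2 lower (median 0.26, adjusted p = 0.0165, adjusted p = 0.423 with an estimated correlation, turning to -0.25, 0.30 above all genes), and antigen presentation 10 of 17 higher and 2 lower (median 0.27, adjusted p = 0.0146, adjusted p = 0.443 with an estimated correlation, turning to -0.24, 0.30 above all genes). In HEPES these lists were not called, with 15 of 30 higher and 7 lower for oxidative phosphorylation (median 0.11, adjusted p = 0.31) and 7 of 13 higher and 0 lower for mitochondrially encoded genes (median 0.21, adjusted p = 0.271). Glycolysis had 10 of 20 higher and 7 lower there (median 0.05, adjusted p = 0.342) and antigen presentation 10 of 17 higher and 4 lower (median 0.24, adjusted p = 0.0746). With total-count scaling these HEPES medians turned to -0.48, -0.38, -0.54 and -0.34, above the median of all genes (-0.67). No difference between the media was called for any of the 4 in the interaction (adjusted p = 0.05, 0.243, 0.228 and 0.859). Hk2, the first enzyme of glycolysis, rose by 2.86 ± 0.06 in MOPS and 3.69 ± 0.06 in HEPES. B cell markers fell in both media, with 0 of 10 higher and 8 lower in MOPS (median -0.72, adjusted p = 0.0424, adjusted p = 0.591 with an estimated correlation) and 0 of 10 higher and 10 lower in HEPES (median -2.02, adjusted p = 0.00264, adjusted p = 0.46 with an estimated correlation). In MOPS that call was lost without MOPS replicate 2 (adjusted p = 0.0542) or 3 (adjusted p = 0.0536) and without MOPS with LPS replicate 8 (adjusted p = 0.0613) or 9 (adjusted p = 0.0717), with 0.00837 to 0.591 over all alternatives.

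Among the genes that fell most, Zfp395 went from 34.2 ± 1.25 to 3.52 ± 0.0431 CPM in MOPS and from 46.4 ± 1.98 to 0.948 ± 0.513 CPM in HEPES, and Dbp, a clock output gene, changed by -3.81 ± 0.071 and -5.31 ± 0.12. Engase changed by -4.39 ± 0.094 and -5.44 ± 0.13. Mki67, a proliferation marker, rose by 3.92 ± 0.068 and 4.23 ± 0.067, while the cell cycle list as a set was not called in MOPS (3 of 20 higher and 8 lower) or HEPES (3 of 20 higher and 10 lower). Dbp lies opposite to Sphk2, so counts at their overlap depend on the strand setting, which is not given in the sources used here.

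LPS raised 4945 genes and lowered 5062 in MOPS, and raised 5168 and lowered 5982 in HEPES (edgeR, adjusted p under 0.05). At least 2-fold changes numbered 1564 higher and 1707 lower in MOPS, and 2010 higher and 2862 lower in HEPES. Scaling by total counts alone moved the median of all genes from -0.03 to -0.55 in MOPS and from -0.08 to -0.67 in HEPES. It gave 2084 higher and 9506 lower in MOPS, 17.98% higher against 49.42%, and 2502 higher and 9666 lower in HEPES, 20.6% against 46.4%. Of the genes raised in MOPS, 4235 were raised in HEPES, where 1762 would be shared by independence, and 155 were lowered there. Of those lowered in MOPS, 4376 were lowered in HEPES (2088 by independence) and 125 raised. The LPS changes correlated across genes with a Pearson r of 0.903 and a Spearman rho of 0.876. The authors' table called 4664 higher and 4181 lower in MOPS, of which 8660 were called here in the same direction, and 5286 and 5121 in HEPES, of which 9933 were, with 0 opposite in either.

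The interaction asked whether the LPS response itself differed between the media. It was called for 5719 genes. Gpr65 fell less with LPS in MOPS (-0.50 ± 0.08) than in HEPES (-2.67 ± 0.088), an interaction of 2.16 ± 0.12. With LPS it stood at 16.1 ± 1.98 CPM in MOPS and 6.76 ± 0.113 CPM in HEPES (SD, n = 3). Bcl6 (2.28 ± 0.11), Tent5c (2.61 ± 0.23), Gpr183 (2.55 ± 0.27) and Tnf (0.82 ± 0.11) had positive interactions too. Tnf was lower in MOPS without LPS, and its difference between the media with LPS did not pass. Its interaction thus goes with its lower untreated level. Gata6 rose with LPS by 2.14 ± 0.055 in HEPES and 0.39 ± 0.057 in MOPS, an interaction of -1.75 ± 0.079 (adjusted p = 8.68e-17, edgeR). With total-count scaling the change of Gata6 in MOPS turned to -0.12, where the median of all genes was -0.55. Ptgs2 (-2.69 ± 0.32), Gpr132 (-1.03 ± 0.12) and Hk2 (-0.83 ± 0.082) had smaller fold responses in MOPS. Of these, Ptgs2 and Gpr132 were higher in MOPS without LPS and lower with it.

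None of the 28 lists was called in the interaction with an estimated correlation between genes. With the preset correlation, lists with negative interactions included the unfolded protein response, 1 of 14 higher and 13 lower (median -0.48, adjusted p = 6.24e-10, adjusted p = 0.39 with an estimated correlation). Herpud1 was at -1.06 ± 0.053 and Hspa5 at -0.84 ± 0.052. The ATF4 integrated stress response had 2 of 20 higher and 14 lower (median -0.51, adjusted p = 8.02e-07, adjusted p = 0.39 with an estimated correlation). Sesn2 was at -1.48 ± 0.078. NF-kappaB feedback genes had 1 of 19 higher and 16 lower (median -0.45, adjusted p = 2.01e-06, adjusted p = 0.39 with an estimated correlation). Traf1 was at -1.29 ± 0.13. TLR4 pathway components had 3 of 20 higher and 10 lower (median -0.15, adjusted p = 0.00937, adjusted p = 0.39 with an estimated correlation). Traf6 was at -0.79 ± 0.061. Inflammatory cytokines, chemokines and enzymes had 4 of 28 higher and 7 lower (median -0.40, adjusted p = 0.0132, adjusted p = 0.495 with an estimated correlation). Il1a was at -0.54 ± 0.084, while Ccl4 went against the list's direction (1.25 ± 0.10). The list's call was lost without MOPS with LPS replicate 8 (adjusted p = 0.0522) or HEPES with LPS replicate 11 (adjusted p = 0.0595), with 0.00105 to 0.495 over all alternatives.

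Sets with positive interactions included cholesterol synthesis and uptake, 15 of 20 higher and 0 lower, or 17 and 0 adjusted over the list alone (median 0.53, adjusted p = 1.27e-05, adjusted p = 0.39 with an estimated correlation), with Mvd at 1.10 ± 0.081, and lysosome genes, 22 of 30 higher and 3 lower, or 24 and 3 adjusted over the list alone (median 0.27, adjusted p = 5.07e-06, adjusted p = 0.39 with an estimated correlation). Rragd was at 1.18 ± 0.11. B cell markers had 8 of 10 higher and 0 lower (median 1.33, adjusted p = 9.09e-04, adjusted p = 0.495 with an estimated correlation). Ighm was at 1.22 ± 0.26. The other 20 lists were not called in the interaction.

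Of the 5719 genes, 3173 had a positive interaction and 2546 a negative one, with 588 and 224 at 2-fold or more. Total-count scaling gave 3891 and 1972, 66.4% positive against 55.5%, and removing a trend on GC content and length from each library gave 2565 and 3195, 44.5% positive. Negative genes were also more numerous with RLE factors (2783 and 2899), DESeq2 (2595 and 2744) and limma-trend on FPKM (2732 and 2966). The same held without MOPS with LPS replicate 7 (2602 and 2938) or 8 (2539 and 2844), or HEPES with LPS replicate 10 (2518 and 2839), 11 (2544 and 2815) or 12 (2509 and 2856). The sign of the excess therefore depends on the setting. By response, 11661 genes changed with LPS on average and 5171 of these had an interaction. Of 5439 genes that LPS raised, 2013 (37.0%) rose less in MOPS and 558 (10.3%) rose more, with a median interaction of -0.17. Of 6222 that LPS lowered, 2309 (37.1%) fell less in MOPS and 291 (4.68%) fell more, with a median of 0.30.

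**Figure D4:**
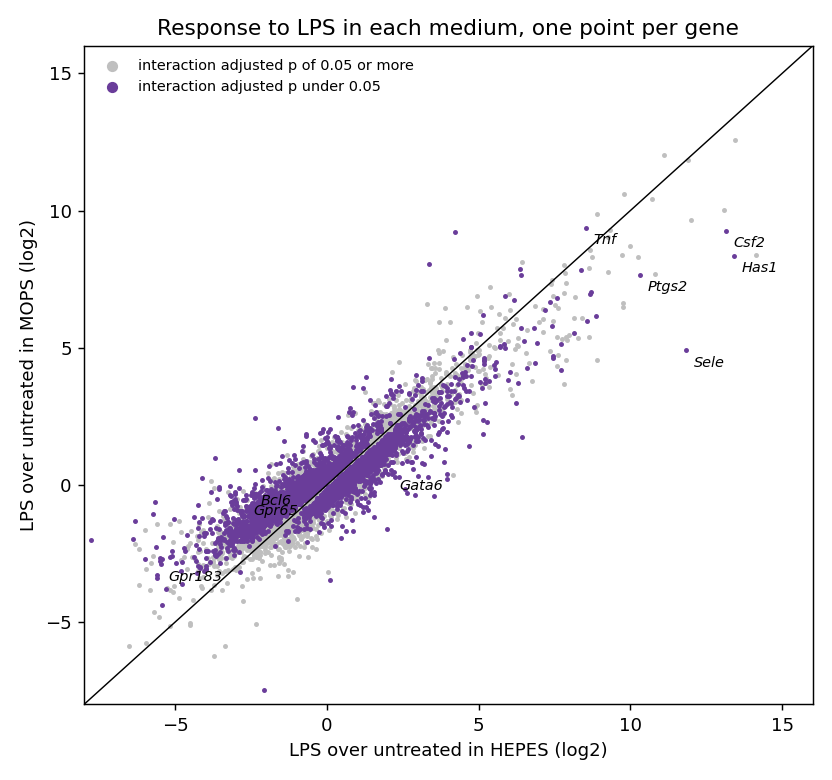
Each point is 1 gene, with its log2 change with LPS in HEPES (x axis) and in MOPS (y axis), purple where the interaction had an adjusted p under 0.05, and the line marks equal change. Gata6 lies at 2.14 in HEPES and 0.39 in MOPS, Ptgs2 at 10.33 and 7.64, while the fitted values of Sele, Has1 and Csf2 in HEPES rest on 0 to 3 untreated counts.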

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

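Of the tests below, the scaling, dilution and macrophage-share tests and those with the GC and length offset were chosen only after the data were seen. The single genes at the end of this section differed between the media in their LPS response by the test of the interaction. The lists there were called with a preset correlation between genes, and none with an estimated one.

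In the first pattern, a smaller LPS response in MOPS medium, the interaction was positive in 3173 genes and negative in 2546 (2783 and 2899 with RLE factors, so neither sign is in excess throughout), and the median interaction of genes lowered by LPS exceeded that of genes raised by 0.4682 (0.4767 with a GC and length trend removed, which argues against that trend). A wrong library factor would shift both alike and leave no gap, and with each library left out in turn the gap was 0.4575 to 0.4993, which argues against scaling. Of 378 genes raised at least 8-fold on average, 118 (31.22%) were called smaller in MOPS, with a median interaction of -0.53 over the 378. Unresponsive cells or RNA would enlarge no response, but 25 (6.614%, 5.344% to 7.214% over left-out libraries) were called larger in MOPS. Without genes at 3 counts or fewer in a group, 23 of 283 were (8.127%, 6.597% to 9.408%). This argues against dilution as the only source of the interactions. A medium difference in untreated levels, as for Tnf, can enlarge a fold while dilution shrinks others. The count therefore does not decide whether dilution shrank the 118. A median of -0.53 would need 30.98% of the RNA in MOPS to be unresponsive, at the same untreated levels. No gene could then fall with LPS in MOPS below a log2 change of -1.69, but 614 called genes did. This argues against dilution of that size and kind as the source of that median. The falls were not tested against the limit. Dilution by a smaller share, or by RNA with other untreated levels, stays open. A response changed by the medium may also account for the smaller responses, as pH or as buffer, which the design cannot separate.

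B cell markers were higher in MOPS medium, with a median interaction of 1.33. A second list of 10 B cell genes, 8 of them measured, had a median of 1.8603 under LPS (1.7138 to 1.8824 over left-out libraries) but 0.38 without LPS, where Cd22 and Bank1 were lower. Ighm, the most abundant, was at 68.0 ± 4.24 CPM in MOPS with LPS against 13.6 ± 0.512 CPM in HEPES with LPS. More B cell RNA in the MOPS libraries may explain the pattern under LPS, but the low median without LPS leaves it open. A lower macrophage share would raise other markers too, but the highest median among T and NK (2 genes measured, near 1 CPM), granulocyte and mesothelial lists was -0.0685 (-0.0696 to 0.1513), and that of dendritic cell and small peritoneal macrophage markers 0.25 (3 of 9 higher, 2 lower) against 1.71 for B cells, which argues against it.

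About 50% of tested genes were called between media at rest, the third pattern. Removing a GC and length trend left 7338 called genes against 7205, which argues against that trend as the cause. The difference in medium, as pH or buffer, stays open as a biological explanation. With no fold minimum, the called genes had a median fold change of 1.31, and the common biological coefficient of variation was 4.62%. The labels do not say whether replicates were separate animals or cultures. A difference in preparation between the groups therefore cannot be told apart from the medium.

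Of the 10 splits of 6 libraries for each comparison, 1, the real one, gave 7469 called genes at rest, 7425 under LPS, 9735 with LPS in MOPS and 10910 with LPS in HEPES, where the highest other split gave 0. These splits are too few for a share under 0.05. In every other split each side holds libraries of both groups. The difference between the groups then adds to the spread and is partly taken out of the contrast, so a low count was fixed in advance. These splits do not decide whether chance gave the counts. For the interaction 100 splits were drawn, of which 2 gave as many genes, the real one with 5719 and another with 8454. In that one the medium labels are exchanged among the LPS libraries only, so it measures the sum of both medium effects, and the highest of the rest gave 3653. For genes changed by LPS with an interaction, 2 of the 100 gave as many, the real one with 5171 and the same exchanged split with 7113, and the highest of the rest gave 2971. All 85 splits that mix the media in both LPS states gave 0 genes. In them the medium effect lies within groups, where it adds to the spread and is partly taken out of the contrast. How much each of these mattered was not tested. These splits therefore do not decide whether chance gave either result of the interaction.

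Single genes with a positive interaction were Tent5c (2.61), Gpr183 (2.55), Thbd (2.42), Zfp395 (2.33), Scml4 (2.32), Bcl6 (2.28), Gpr65 (2.16), Tnf (0.82) and Ldha (0.18). Gpr183 lies opposite to Ubac2. Tnf was lower in MOPS without LPS, and its difference between the media with LPS did not pass. Ldha was not called by DESeq2 (adjusted p = 0.0541) or by edgeR with the GC and length offset (0.08, adjusted p = 0.19). Its call was also lost without MOPS with LPS replicate 7 (adjusted p = 0.157) or any HEPES with LPS library (adjusted p = 0.0645 to 0.131). Over all alternatives its adjusted p was 3.55e-04 to 0.19. Genes with a negative interaction were Sele (-6.95), Has1 (-5.07), Csf2 (-3.90), Penk (-3.28), Shisa3 (-2.82), Gfpt2 (-2.74), Cxcl3 (-2.71), Gpr132 (-1.03), Ptgs2 (-2.69), Hk2 (-0.83), Gata6 (-1.75) and Abca1 (-0.24). Sele, Has1 and Csf2 had 0 to 3 untreated counts in HEPES, so their fitted values are no measure of size. Without MOPS replicate 2, Sele was at -5.21 (adjusted p = 1), Has1 at -5.67 and Csf2 at -3.98 (adjusted p = 0.0532). Without MOPS replicate 1, Has1 was at -4.36 (adjusted p = 0.0818). Without MOPS replicate 3, Has1 was at -4.87 (adjusted p = 0.0514), Csf2 at -2.94 (adjusted p = 0.201) and Shisa3 at -2.38 (adjusted p = 0.0998). Without HEPES replicate 5, Csf2 was at -4.71, Shisa3 at -4.29 and Cxcl3 at -3.76. Over all alternatives the adjusted p was 8.68e-04 to 1 for Sele, 0.00197 to 0.0818 for Has1, 3.99e-04 to 0.201 for Csf2 and 0.00207 to 0.0998 for Shisa3. Shisa3 lies opposite to Atp8a1.

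The lists called in the interaction with a preset correlation had medians of 0.53 for cholesterol synthesis, 0.27 for lysosome, -0.51 for ATF4, -0.48 for the unfolded protein response, -0.45 for NF-kappaB feedback, -0.40 for cytokines and -0.15 for TLR4 components. With an estimated correlation all of these calls were lost (adjusted p = 0.39 to 0.495), and that of cytokines also without MOPS with LPS replicate 8 (adjusted p = 0.0522) or HEPES with LPS replicate 11 (adjusted p = 0.0595).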

How the results depend on the processing

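The scaling by total counts alone, the GC and length offset, the list counts and the left-out list tests were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. The counts of called genes stayed within 1.5 times their value under RLE factors, DESeq2, no filter, the groups of the contrast alone, limma-trend on FPKM, the GC offset and each left-out library. Requiring a 2-fold change gave, by construction, 487 higher and 690 lower at rest, 899 and 624 under LPS, 1564 and 1707 with LPS in MOPS, 2010 and 2862 in HEPES, 588 and 224 in the interaction, and 578 LPS-responsive genes with an interaction. Total counts alone gave 2084 and 9506 with LPS in MOPS and 2502 and 9666 in HEPES, since LPS libraries have lower composition factors. With it the median of all genes was -0.55 in MOPS and -0.67 in HEPES, and changes with LPS in MOPS turned to -0.28 for Mdh2, -0.15 for mt-Nd1, -0.19 for mt-Cytb, -0.18 for mt-Nd4, -0.17 for mt-Nd2 and -0.12 for Gata6, and in HEPES to -0.11 for Atp5b, -0.31 for mt-Co1, -0.29 for mt-Nd5, -0.33 for mt-Nd1, -0.34 for mt-Cytb and -0.20 for Ldha. Summed over the contrasts, camera gave 55 list calls, of which 8 held with an estimated correlation. Fry, which does not set a list against other genes, gave 102. What made these counts differ was not tested. Over left-out libraries the counts were 3151 to 3637 higher and 3294 to 3740 lower at rest, 3272 to 3933 and 3668 to 4180 under LPS, 4743 to 4993 and 4782 to 5155 with LPS in MOPS, 5050 to 5489 and 5511 to 6070 in HEPES, 2509 to 3000 and 2332 to 2938 in the interaction, and 4740 to 5006 LPS-responsive genes with an interaction. Calls on named genes, each gene counted once per contrast, numbered 628 in all contrasts together, and 620 to 630 over left-out libraries. DESeq2 lost 6 named calls and gained 7, RLE lost 1 and gained 2, the GC offset lost 6 and gained 4, and total counts lost 19 and gained 11. Summed over the runs with each library left out, 67 named calls were lost and 30 gained. Counts of called members per list moved by over 1.5 times in 199 cases with the 2-fold minimum, 85 with total counts, 12 with DESeq2, 9 with no filter and 7 with RLE. For 5 results on named genes DESeq2 gave no adjusted p, so these have no value. With 1 library left out some lists gained a call: ATF4 genes at rest (adjusted p = 0.0456 without HEPES replicate 5, 0.0349 without 6; 0.00287 to 0.693 over all alternatives), TLR4 components under LPS (0.0437 without HEPES with LPS replicate 12; 5.77e-05 to 0.471), cAMP-CREB targets under LPS (without MOPS with LPS replicates 8 or 9 or any HEPES with LPS library; 3.16e-05 to 0.471) and in HEPES (without HEPES replicate 6; 2.37e-08 to 0.46), proton sensing in HEPES (without MOPS replicates 1 or 2 or HEPES replicates 4 or 6; 1.41e-09 to 0.371), and oxidative phosphorylation in the interaction (without MOPS replicate 2 or HEPES replicates 4 or 6; 0.0124 to 0.831). Members of lists at 3 counts or fewer, set to their bound, left list medians as they were, except for dendritic cell markers in the interaction, which went from 0.36 to 0.37. The depth limits genes near the floor, whose fold changes rest on few counts.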

Other observations

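The families of genes below were defined by symbol after seeing the data, and all tests in this part were chosen then. Of 24 families tested, the circadian clock genes, listed after the change of Dbp was seen, were higher in MOPS without LPS, 11 of 15 with 2 lower (median log2 change 0.83, adjusted p = 2.68e-05 by camera, and adjusted p = 0.0223 with an estimated correlation). Among them, chosen after their values were seen, Nr1d1 was at 2.02 ± 0.064, Per3 at 0.95 ± 0.074 and Dbp at 1.52 ± 0.054, while Arntl was at -0.58 ± 0.088. With LPS 12 were higher and 3 lower (median 0.95, adjusted p = 6.31e-04, and adjusted p = 0.0505 with an estimated correlation). The labels give no time of collection. V-ATPase subunits, which acidify lysosomes, were lower in MOPS without LPS, 16 of 18 with 1 higher (median -0.25, adjusted p = 2.68e-05, and adjusted p = 0.376 with an estimated correlation). With LPS 11 of these subunits were lower and 0 higher (median -0.13, adjusted p = 0.00772, and adjusted p = 0.477 with an estimated correlation). They were not called in the interaction (adjusted p = 0.481 by camera).

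Proteasome subunits rose with LPS, 38 of 44 in MOPS (median 0.56, adjusted p = 9.42e-10, and adjusted p = 0.0975 with an estimated correlation) and 39 in HEPES (median 0.60, adjusted p = 1.13e-08, and adjusted p = 0.069 with an estimated correlation). With total-count scaling these medians were 0.04 and 0.01, where those of all genes were -0.55 and -0.67. Ribosome biogenesis genes had negative interactions, 26 of 39 with 2 positive (median -0.33, adjusted p = 4.37e-07, and adjusted p = 0.0369 with an estimated correlation). RNA helicases of the Ddx and Dhx families did too, 30 of 51 with 1 positive (median -0.22, adjusted p = 4.23e-07, and adjusted p = 0.0369 with an estimated correlation). So did nucleoporins, 9 of 20 with 1 positive (median -0.28, adjusted p = 6.66e-04, and adjusted p = 0.0369 with an estimated correlation). The medians of these families kept their sign with total-count scaling, at -0.26, -0.14 and -0.21 in that order. Aminoacyl-tRNA synthetases, translation initiation factors, proteasome subunits and deubiquitinases had negative median interactions called by camera with the preset correlation alone. Zinc finger genes named Zfp fell with LPS in MOPS, 198 of 327 with 48 higher (median -0.49, adjusted p = 5.15e-05, and adjusted p = 0.0223 with an estimated correlation), and in HEPES 174 were lower and 83 higher without a call (adjusted p = 0.0667). The difference between the media was not called for them either (interaction adjusted p = 0.0586). Long intergenic RNAs, 384 of them tested, had medians with LPS of -0.55 in MOPS and -0.91 in HEPES with TMM scaling. Those of all genes with that scaling were -0.03 and -0.08. In MOPS 68 were higher and 153 lower, and in HEPES 77 were higher and 205 lower. As a set they were not tested against other genes.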
